A study of Mus musculus with 4 samples.

How the data were processed

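Total RNA of 2 preps of thymic CD8+ cells and 2 preps of in vitro-derived CD8+ cells was extracted with Trizol, and 1 ug of each was amplified and labelled with the Agilent Low RNA Input kit, per the labels' protocols. Thymic RNA was labelled with Cy3 and in vitro-derived RNA with Cy5, per the labels, and dyes were not swapped. Each of the 4 arrays paired 1 thymic prep with 1 in vitro prep, so that every combination of preps was hybridised once. All 4 arrays lay on 1 slide and were read in 1 scan, so slide and scan do not split the arrays.

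The authors deposited 1 scanner file per array, which holds spot intensity values (mean signal and local background of each channel) on a linear scale, written by Agilent Feature Extraction 9.5.1.1 per the file headers. Feature Extraction had also subtracted background and normalized the dyes in its processed signals, per the file headers. The deposited series table holds a log10 ratio of Cy5 over Cy3 for each probe. Its scale and direction were found by setting it against the scanner's own log ratio, averaged over the spots of a probe. The correlation across probes was at least 0.9999 on each array, and 99.4% to 99.5% of values were equal within 0.0001. The median of each of its 4 columns was 0, and 6119 to 7234 probes per array were listed at exactly 0, which is no measured equality. The submitters' processing notes name Agilent Feature Extraction. Its version there is not given in the sources used here.

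Log ratios were computed here from mean signals and median local backgrounds with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0 and no scaling between arrays. Spots marked by Feature Extraction as non-uniform, as population outliers or as having a non-uniform background (133 to 187 per array) were left out before the background model was fitted. This last step was chosen after the data had been seen. In a first pass the model was fitted on all spots and spots with a feature mark were left out after it. On array 3 it gave a mean Cy5 background of -878, against -9.38 without the marked spots, because 3 spots there lie far below their own local background, which reached 59046. The first pass called 7427 genes (3470 higher, 3957 lower) and 11 lists, and the choice raised this to 9975 genes (5115 higher, 4860 lower) and 12 lists. Of these genes 7394 genes were called in both, 2581 only with the marked spots left out first and 14 only in the first pass, which called a further 19 genes that were tested only there. Both are reported, and where a named gene or list loses its call with the fit on all spots this stands beside its value. Saturated spots (1 in Cy5 on each array) were kept.

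Probes were tested where they were well above background on all 4 arrays in at least 1 channel and had a value on all 4 arrays, which left 27224 of 41174 probes. The scanner software calls a spot well above background from the spread of the background. Spots of 1 probe were averaged, and 1 probe, that of highest mean intensity, stood for each gene. Gene names were updated through RefSeq accessions of the GRCm38.p6 annotation, where 22951 of the 41174 probes matched and 5141 names changed. The other names are those of the array design, and no coordinates are given because the build of the array design is not given in the sources used here. Other probes of called genes had the same sign in 4365 of 5043 cases (86.6%), and in 1036 of 1075 (96.4%) for genes called at least 2-fold. Of the 194 named genes 90 had 2 or more tested probes, and 7 had probes called in both directions. Where a gene was not well above background on any array in 1 channel, the difference is given as at least N-fold, from channel values after loess and Aquantile normalization, and it is open to dye bias.

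The 4 log ratios of each gene were turned into 4 prep values, 2 per kind, whose difference between kinds is the mean log ratio, because each prep was used on 2 arrays and the arrays are not independent. Differences were tested with lmFit and eBayes (2 residual degrees of freedom, prior degrees of freedom 3.04), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Errors are standard errors of this fit. On simulated data with 200 of 19154 genes changed, over 10 runs, the fit called 1.0% of genes changed 1.25-fold, 23.2% of those changed 1.5-fold, 83.2% of those changed 2-fold and 97.0% of those changed 4-fold, and 3.0% of its calls were false. With the 4 arrays taken as independent, 62.4% of calls were false. In the data 9975 genes were called, far more than the 200 changed here, and the Benjamini-Hochberg cut-off depends on that share. These percentages therefore hold for the simulated setting only. The 30 gene lists were tested with camera (two-sided, preset correlation of 0.01, at least 5 tested members) with Benjamini-Hochberg adjustment over lists, again with an estimated correlation, and with fry. With an estimated correlation camera rests on the 2 residual degrees of freedom, so it could hardly pass any list. With the preset correlation it rests on the number of genes. On simulated lists camera found 20 of 20 moved lists and 0 of 20 that were not moved. The simulated genes were drawn independently of each other, so this does not cover lists whose members vary together. Such lists include the T cell receptor complex (estimated correlation 0.89) and the cell cycle (0.48). Differences between preps of a kind are described without a test, beside the percentile of a list's median among 10000 random lists of the same size matched on expression.

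The groups, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Named genes were the 15 with the highest and the 15 with the lowest log ratio among called genes with the same sign on all 4 arrays, leaving out names of clones, accessions and predicted genes. From each list came up to 4 called members with the smallest p and up to 2 tested members not called with the highest intensity. They were joined by a set of key genes of CD8 T cells whatever their value. Of these, Zbtb16 had no probe of that name, and some genes that the rule names are not reported here.

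Median signal per array was 90.7 to 97.3 in Cy3 and 196 to 215 in Cy5, over a median local background of 30 to 31.5 and of 49. Spiked-in control transcripts gave a slope of measured on known log ratio of 0.892 to 0.898. The alternatives tried were no background correction, Agilent's processed signals, an offset of 16, the background fit on all spots, median centring in place of loess, channel values after Aquantile, the deposited log ratios, no filter on dim probes, a filter on both channels, marked spots kept, the mean over probes of a gene, arrays as independent, arrays with the thymic or the in vitro prep as a random block, eBayes with a trend or robust, prep number as a block, and leaving out each prep and each array in turn. Control spots were left out of all tests. Figures were drawn with python 3.11.15.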

Results

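Gene expression was compared between murine CD8+ T cells made in culture and CD8+ cells taken from the thymus, both of C57Bl/6 origin. The cultured cells came from sorted haematopoietic stem and progenitor cells of bone marrow grown for 35 days on OP9-DL1, a bone marrow stromal line that displays the Notch ligand Delta-like 1, with the cytokines Flt3 ligand and IL-7. Marrow donors were 6 to 8 weeks old and thymus donors 4 to 5 weeks old. Donor age therefore cannot be told apart from the origin of the cells. Both kinds of cells were sorted for CD8 and high T cell receptor beta. There were 2 RNA preps of each kind, and each prep was hybridised against both preps of the other kind, giving 4 Agilent arrays. Thymic RNA carried Cy3 and in vitro-derived RNA carried Cy5 on all 4 arrays, so an effect of the dye on a probe cannot be told apart from the difference between the cells. The labels speak of biological replicates but name no separate animals, so the p-values measure the spread between these preps. Of the 43379 spots that were not controls, 63.7% to 65.6% were well above background in Cy3 and 66.5% to 70.9% in Cy5, and 19154 genes were tested. The number of preps limits the precision: with 2 against 2, an exact permutation test of a single gene cannot give a p under 0.333, and the calls therefore rest on a variance shared over genes.

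The first question was which genes differ between in vitro-derived and thymic CD8+ cells. Dntt, the terminal transferase that adds nucleotides at V(D)J junctions, was 66.1-fold higher in in vitro-derived cells on the probe used, with a log2 difference of 6.05 ± 0.19 (SE, n = 2 preps of each kind), and lay at 4.82 as a mean over its 3 probes. Gzma, a cytotoxic granule protease, was 63.7-fold higher (5.99 ± 0.09), Arpp21, a gene of immature thymocytes, 48.9-fold higher (5.61 ± 0.12) and Tcrg, a transcript of the T cell receptor gamma locus, 28.3-fold higher (4.82 ± 0.06). At the other end, the interferon-induced gene Ifi27l2a was 27.7-fold lower (-4.79 ± 0.07), the sialyltransferase gene St3gal6 27.2-fold lower (-4.76 ± 0.06), Bcl2a1b, an anti-apoptotic member of the Bcl2 family, 24.2-fold lower (-4.60 ± 0.06) and the chemokine receptor gene Cxcr6 23.4-fold lower (-4.55 ± 0.16).

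The 15 genes with the largest increases also held Syt13 (5.95), the myosin gene Myo6 (5.59), Myl10 (5.13), Tspan2 (5.03), Rapgef3 (4.96), Endou (4.95), Tcrg-C (4.77), the platelet-derived growth factor receptor gene Pdgfrb (4.69), Pdlim4 (4.62), the tubulin gene Tubb2b (4.43) and Strip2 (4.40). The genes with the largest decreases also included the interferon-induced genes Ifit1 (-4.39) and Oas2 (-4.00), Pacsin1 (-4.39), the cholesterol efflux transporter gene Abca1 (-4.16), the death receptor gene Tnfrsf25 (-4.15), Lrig1 (-3.92), the alpha-fetoprotein gene Afp (-3.88), Atp11a (-3.77), Crtam (-3.76) and Tspan9 (-3.71). The adjusted p was 3.9e-04 for Myo6, whose preps differed most, and no higher than 5.9e-05 for the others named here. As a mean over the probes of a gene, Strip2 moved to 1.94, Arpp21 to 4.19, Syt13 to 3.73, Myo6 to 4.56, Tspan2 to 3.70, Pdlim4 to 3.67, Ifi27l2a to -4.20, Pacsin1 to -3.60, Tnfrsf25 to -2.53, Oas2 to -2.42, Atp11a to -2.27 and Tspan9 to -3.09. With Agilent's processed signals, Strip2 moved to 6.33, Pdgfrb to 5.91, Tcrg-C to 5.38, St3gal6 to -5.96, Abca1 to -5.25, Bcl2a1b to -5.21 and Atp11a to -4.65. The order of these genes by size therefore holds only for the probes and the setting used.

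In all, 9975 of the 19154 genes (52.1%) passed an adjusted p of 0.05 in limma, 5115 higher and 4860 lower in in vitro-derived cells, each with the same sign on all 4 arrays. Of these, 2147 differed at least 2-fold (1189 higher, 958 lower) and 502 at least 4-fold (288 higher, 214 lower). The balance of directions is set by the intensity-dependent normalization: with median centring in its place the median of all genes moved from 0.03 to 0.39 and 84.1% of calls were higher against 51.3%. With it, 1291 called genes were called in the opposite direction. A background model fitted on all spots, including 3 spots with a very bright local background on array 3, gave 7427 calls, and the choice to leave such spots out before the fit was made after that result had been seen. Leaving out 1 thymic prep left the spread to the 2 in vitro-derived preps alone (SD of their difference 0.196). Leaving out 1 in vitro prep left it to the 2 thymic preps (SD 0.106). A call lost or gained on leaving out 1 prep, here and below, can therefore come from that spread and not from the prep left out. Markers of stromal cells, given further on, were also higher in in vitro-derived cells (median 1.21), in the same comparison as the gene groups that follow.

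**Figure D1:**
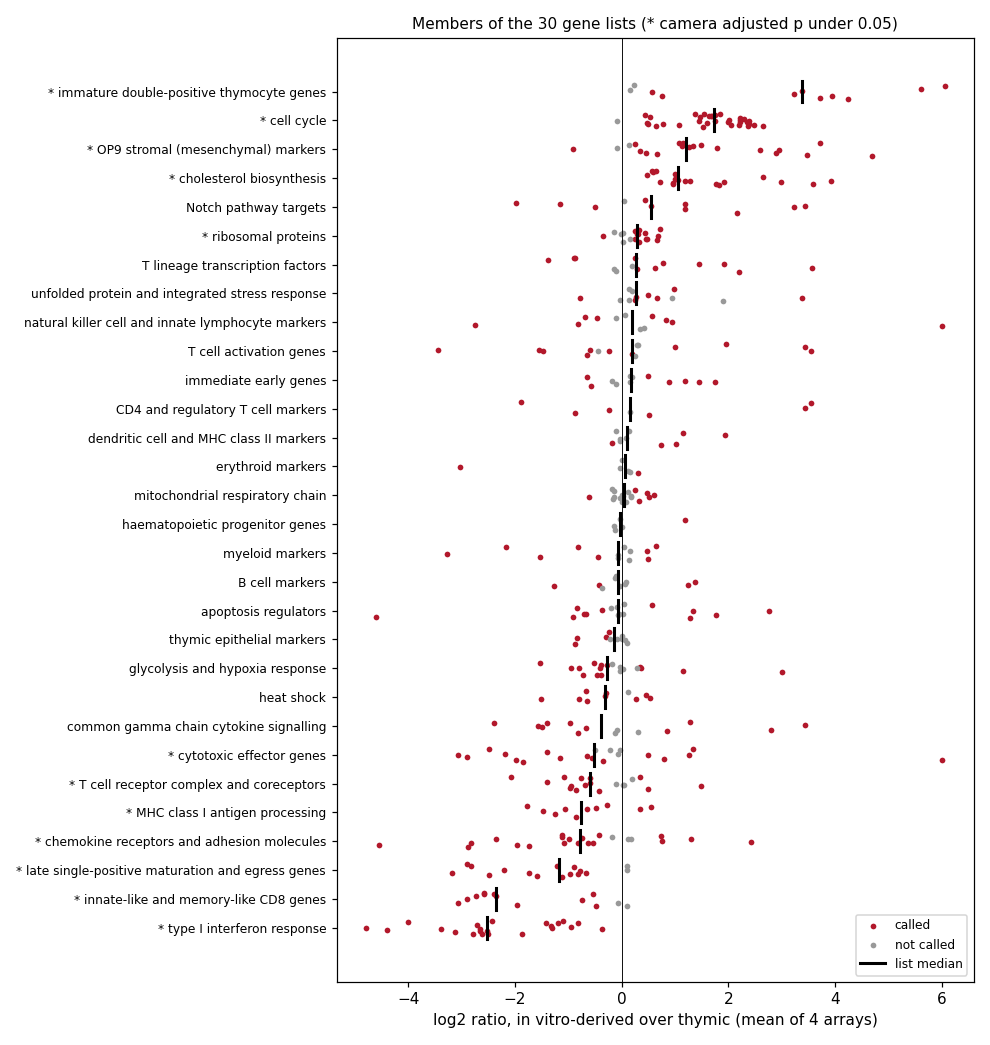
Log2 ratio of in vitro-derived over thymic cells (horizontal axis, mean of 4 arrays) for the tested members of 30 gene lists (vertical axis, ordered by list median). Each point is 1 gene, red where it was called and grey where it was not, black bars are list medians, and an asterisk marks the 12 lists with a camera adjusted p under 0.05 at its preset correlation. None passed with an estimated correlation, a test on 2 residual degrees of freedom that could hardly pass a list. The medians run from 3.38 for immature thymocyte genes to -2.52 for the interferon response, and with median centring those of the T cell receptor complex and MHC class I lists turn from -0.59 and -0.75 to 0.40 and 0.41.

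Genes of immature, CD4 and CD8 double-positive thymocytes were higher in in vitro-derived cells. Besides Dntt and Arpp21, these included the recombinase gene Rag1 (4.23 ± 0.12, 18.8-fold), Ptcra, which encodes the pre-T cell receptor alpha chain (3.24 ± 0.07, 9.42-fold), the maturation marker Cd24a (3.38 ± 0.06, 10.4-fold) and the aquaporin gene Aqp11 (3.72 ± 0.06, 13.1-fold). Of 11 tested members 9 rose and 0 fell, with a median of 3.38 (camera adjusted p = 4.2e-06, and adjusted p = 0.60 with an estimated correlation). Here and below, the value with an estimated correlation rests on 2 residual degrees of freedom. It could hardly be small for any list and decides little. The coreceptor gene Cd4 itself differed by 0.15 ± 0.06 (adjusted p = 0.12) and Cd1d1 by 0.23 ± 0.16 (adjusted p = 0.31), neither called, although the other probe of Cd4 was called higher.

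The T cell receptor complex and its coreceptors went mostly the other way. Cd8a fell by 0.76 on the log2 scale (SE 0.10), Cd8b1 by 0.95 (SE 0.21), the receptor chains Cd3e by 0.42 (SE 0.06) and Cd3g by 0.70 (SE 0.07), and Ptprc, the CD45 phosphatase gene, by 0.85 (SE 0.08), but these 5 turned with median centring to 0.42, 0.38, 0.26, 0.44 and 0.36. Cd3e was not called without thymic prep 1 (-0.40), nor Cd8b1 with marked spots kept (-0.91). The kinase gene Fyn fell by 1.07 (SE 0.06), while Cd28, a costimulatory receptor gene, went against the list and rose by 1.48 (SE 0.08). Of 18 tested members 3 rose and 11 fell, with a median of -0.59 that became 0.40 with median centring (camera adjusted p = 0.026, and adjusted p = 0.79 with an estimated correlation). The list's call was also lost with Agilent's processed signals (-0.60) and without in vitro prep 2 (-0.56). Cd3d (0.02) and the adaptor gene Lat (0.20) were not called, but both were called higher with median centring (1.26 for Cd3d).

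Among T lineage transcription factors, 8 of 14 rose and 3 fell (median 0.27, camera adjusted p = 0.19). Myb (3.56 ± 0.07), Gata3 (2.20 ± 0.08) and Tcf12 (1.92 ± 0.08) were higher, and Foxo1, a regulator of naive T cell homing and survival, was lower (-1.39 ± 0.07). Lef1 (-0.15) and Satb1 (0.20) were not called. With median centring both were called higher (0.98 and 1.31), while Satb1 was called lower as a mean over its probes (-0.40) and Lef1 without in vitro prep 1 (-0.41).

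Genes that mark late maturation of single-positive cells and exit from the thymus were lower in in vitro-derived cells. Ccr7, a chemokine receptor gene for medullary and lymph node homing, was 7.09-fold lower (-2.83 ± 0.14), Cd52 9.01-fold lower (-3.17 ± 0.06) and Slfn1 7.43-fold lower (-2.89 ± 0.06). The integrin gene Itgb7 was 3.35-fold lower (-1.74 ± 0.06, or -0.62 with median centring). Of 16 tested members 14 fell and 0 rose, with a median of -1.17 that became -0.46 with median centring (camera adjusted p = 2.9e-06, and adjusted p = 0.42 with an estimated correlation). Il7r, the interleukin 7 receptor alpha gene, fell by 0.98 (SE 0.12) and the survival gene Bcl2 by 0.67 (SE 0.11); with median centring the call of Il7r was lost (-0.23) and Bcl2 turned to 0.24. S1pr1, the receptor gene for egress, lay at -0.82 ± 0.25 (adjusted p = 0.043), a call lost with median centring (-0.13), with Agilent's processed signals (-0.87), with the background fit on all spots, with marked spots kept, with an offset of 16, with Aquantile and without thymic prep 1 (-0.83) or prep 2 (-0.81). Klf2, which drives S1pr1, has no clear direction: it was not called on the probe used (0.09 ± 0.08), and its other probe was called lower (-2.23 ± 0.18). With median centring the probe used was called higher (1.30), a setting that raises bright genes such as Klf2, as given below. Ly6c1 was not called (0.11), but was called higher with median centring (0.75) and without in vitro prep 2 (0.22).

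Genes of innate-like and memory-like CD8 cells were lower too. Eomes, a transcription factor gene of such cells, was 5.97-fold lower (-2.58 ± 0.09, or -4.16 with Agilent's processed signals). Its mean log2 level in in vitro-derived cells was 6.23. This lay below Klra8 (6.25), which was not well above background there, so the fold may be larger. Il2rb, the interleukin receptor beta chain gene, was 5.25-fold lower (-2.39 ± 0.14), the adhesion receptor gene Cd44 3.87-fold lower (-1.95 ± 0.07, with 1 of its 3 probes not lower). Cxcr3 was 5.10-fold lower (-2.35 ± 0.06) and the granule gene Nkg7 7.47-fold lower (-2.90 ± 0.08). Of 13 tested members 11 fell and 0 rose, with a median of -2.35 (camera adjusted p = 1.1e-05, and adjusted p = 0.42 with an estimated correlation). Fasl (-0.07) was not called on the probe used, but was lower on its other probe (-0.34) and as a mean over its probes (-0.21). The array held no probe under the name Zbtb16.

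Cytotoxic effector genes went in both directions. Prf1, which encodes perforin, was 5.60-fold lower (-2.49 ± 0.06), the granule protease gene Ctsw 8.32-fold lower (-3.06 ± 0.07) and Ifng, which encodes interferon gamma, 3.62-fold lower (-1.85 ± 0.24), whereas Gzma went against the list. Gzmb did not differ beyond its spread (-0.03 ± 0.48), as it lay at 0.73 without in vitro prep 1 and at -0.79 without in vitro prep 2. Of 20 tested members 5 rose and 11 fell (12 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 0.049, and adjusted p = 0.60 with an estimated correlation). This list's call was lost with the background fit on all spots, with Agilent's processed signals (median -1.36), with marked spots kept, with the filter on both channels (-0.75), without array 3 (-0.52) and without in vitro prep 1 (-0.43).

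Among chemokine receptors and adhesion molecules, Itgae, the CD103 integrin gene, was 7.37-fold lower (-2.88 ± 0.09), next to the lower values of Cxcr6, Cxcr3, Ccr7 and Itgb7. The follicular homing receptor gene Cxcr5 was 5.38-fold higher (2.43 ± 0.07). Of 22 tested members 15 fell and 4 rose, with a median of -0.78 (camera adjusted p = 0.0023, and adjusted p = 0.42 with an estimated correlation). Itga4 (0.11) was not called, with 1 of its other probes called higher and 1 lower, and neither was Itgb3 (-0.17, or 0.58 with median centring).

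All 22 tested members of the type I interferon response fell in in vitro-derived cells. Besides Ifi27l2a, Ifit1 and Oas2, the antiviral genes Oasl2 (-3.38 ± 0.07, 10.4-fold) and Mx1 (-3.12 ± 0.06, 8.70-fold) were lower. Mx1 had the same low level as Eomes in in vitro-derived cells (6.23), so its fold may be larger. The median was -2.52 (camera adjusted p = 6.2e-13, and adjusted p = 0.42 with an estimated correlation). Genes of MHC class I antigen processing fell in 8 of 10 and rose in 2. The heavy chain genes H2-K1 (-1.77 ± 0.07, 3.42-fold) and H2-D1 (-1.48 ± 0.07, 2.79-fold), the peptide transporter gene Tap1 (-1.06 ± 0.06) and Tapbp, the tapasin gene (-1.24 ± 0.07), were lower, and 1 of the 2 probes of H2-D1 was not. With median centring these 4 shrank to -0.41, -0.27, -0.39 and -0.27. The median of -0.75 (camera adjusted p = 0.0061, and adjusted p = 0.60 with an estimated correlation) became 0.41 with median centring, which ended the call.

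Cell cycle genes were higher in in vitro-derived cells. Mki67, the proliferation marker, was 4.65-fold higher (2.22 ± 0.15), the mitotic cyclin gene Ccnb1 6.23-fold (2.64 ± 0.12), the replication genes Pcna 2.90-fold (1.53 ± 0.07) and Cdc6 3.19-fold (1.68 ± 0.06), and Tyms, for thymidylate synthesis, 3.36-fold (1.75 ± 0.07). Of 34 tested members 33 rose and 0 fell, with a median of 1.72 (camera adjusted p = 3.7e-12, and adjusted p = 0.60 with an estimated correlation). The helicase gene Mcm2 alone was not called (-0.08, or 0.76 with median centring). All 19 tested members of the cholesterol biosynthesis list rose as well, with a median of 1.05 (camera adjusted p = 3.2e-09, and adjusted p = 0.42 with an estimated correlation). The squalene epoxidase gene Sqle was 3.59 ± 0.08 higher on the log2 scale and the isomerase gene Idi1 6.25-fold higher (2.64 ± 0.06).

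Ribosomal protein genes rose in 12 of 18 and fell in 1, with a median of 0.29 that became 1.63 with median centring (camera adjusted p = 0.021, and adjusted p = 0.74 with an estimated correlation). Rps16 (0.67, or 2.08 with median centring), Rps3 (0.66, or 1.98) and Rpl7 (0.48) rose on the probes used, but another probe of Rps3 (-0.24) and another of Rpl7 (-0.21) were called lower. Rpl11 lay at 0.73 but at -0.22 as a mean over its probes, and Rpl13 (-0.01, or 1.36 with median centring) was not called. The list's call was lost with Agilent's processed signals, as a mean over probes, without in vitro prep 2 (0.24) and without thymic prep 2 (0.28). Of 18 respiratory chain genes 5 rose and 1 fell. Those that rose included Atp5b (0.60, or 0.20 and not called as a mean over its probes), Cox7a2 (0.50) and Atp5a1 (0.48). Ndufa4 fell (-0.61, or 0.44 with median centring). The list had a median of 0.05 (camera adjusted p = 0.51) that became 1.04, and passed, with median centring. Cox4i1 (0.12) and Cox5a (-0.14, or 0.99 with median centring) were not called.

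Of 19 genes of glycolysis and the hypoxia response 4 rose (5 adjusted over the list alone) and 10 fell, with a median of -0.27 that became 0.64 with median centring (camera adjusted p = 0.19). The oxygen sensor gene Egln3 (7.98-fold higher) and Aldoc (1.15 ± 0.11) rose. The glucose transporter gene Slc2a3 (-0.94 ± 0.06, though its other probe was called higher) and Pdk1 (-0.81 ± 0.06, or -0.084 and not called with median centring) fell. Pgk1 (0.03) and Ldha (-0.04) were not called. Ldha was called higher with median centring (1.14), but lower on its other probe (-0.45) and as a mean over its probes (-0.25).

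Stress genes showed no common direction. In the list of the unfolded protein and integrated stress responses 6 of 13 rose (7 adjusted over the list alone) and 1 fell, with a median of 0.26 (camera adjusted p = 0.17) that passed without in vitro prep 1 (0.33). Asns, the asparagine synthetase gene, was 10.4-fold higher but varied between preps (3.38 ± 0.64, or 4.39 without in vitro prep 1 and 2.38 without in vitro prep 2). Sdf2l1 (0.26) and Xbp1 (0.25) lost their calls with the background fit on all spots, with marked spots kept, with Agilent's processed signals and without either thymic prep (0.22 and 0.29 without prep 1, 0.30 and 0.20 without prep 2). Sdf2l1 also lost its call without in vitro prep 2, and Xbp1 without in vitro prep 1 and without array 1, 3 or 4. The chaperone gene Hspa5 fell by 0.78 but turned to 0.18 with median centring, and Atf4 (0.19) and Herpud1 (0.15) were not called. Of 10 heat shock genes 3 rose and 6 fell, with a median of -0.30 that became 0.61 with median centring (camera adjusted p = 0.32). Hspa8 rose by 0.53, a call lost without thymic prep 2 (0.49) and as a mean over its probes (0.28), and Hsph1 fell by 1.51, whereas the lower values of Hspe1 (-0.67) and Dnaja1 (-0.66) turned to 0.31 and 0.40 with median centring, and Hsp90aa1 (0.11) was not called.

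Because the culture supplies a Notch ligand, Notch pathway genes were examined as a group, and they went in both directions. Notch3 rose by 2.16 (SE 0.07), Heyl by 1.18 (SE 0.06) and Notch1 by 0.54 (SE 0.06), while Hey1 fell by 1.97 (SE 0.12) and Dtx1 by 1.15 (SE 0.12, or -0.22 and not called with median centring). Hes1, a direct Notch target, was at least 1.35-fold higher, because its thymic signal was not well above background, and lost its call with the background fit on all spots. Of 11 tested members 7 rose and 3 fell, with a median of 0.54 that became 1.81 with Agilent's processed signals (camera adjusted p = 0.14; passed without the detection filter), and Hes5 (0.03) was not called. In common gamma chain cytokine signalling 4 of 14 rose (5 adjusted over the list alone) and 7 fell, with a median of -0.40 that became 0.34 with median centring (camera adjusted p = 0.32). Socs2 (2.81 ± 0.14) and the interleukin 2 receptor alpha gene Il2ra (3.44 ± 0.26) rose, the shared receptor chain gene Il2rg (-1.57 ± 0.07) and Il4ra (-1.40 ± 0.07) fell. Stat5b (0.30) and Socs3 (-0.10) were not called. Stat5b was called higher with median centring, with Aquantile, with prep number as a block and without in vitro prep 2 (0.44), but lower as a mean over its probes (-0.23), and Socs3 was called higher with median centring (0.68).

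T cell activation genes rose in 5 of 15 and fell in 6 (7 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.85, with the test pointing down). The inhibitory receptor gene Ctla4 was 11.6-fold higher (3.54 ± 0.10), the costimulatory receptor gene Icos 10.8-fold lower (-3.44 ± 0.12), Egr3 (-1.55) and Tnfrsf9 (-1.47) were lower, and Cd69 (0.29) and Myc (0.31) were not called. Immediate early genes rose in 5 of 12 and fell in 2, with a median of 0.18 (camera adjusted p = 0.34) that passed without thymic prep 1 (0.48). Fosb (1.74 ± 0.25), Egr1 (0.88 ± 0.11) and Atf3 (0.50 ± 0.09, or 1.53 with Agilent's processed signals; not called without thymic prep 1) rose. Ier2 fell by 0.65 but turned to 0.21 with median centring and was not called without in vitro prep 1 (-0.59) or as a mean over its probes (-0.39). Btg2 (0.20) was not called, although both of its other probes were called higher, as was it as a mean over probes (0.27) and without in vitro prep 1 (0.26). Junb (-0.18 ± 0.51) lay at 0.61 without thymic prep 1 and at -0.98 without thymic prep 2. Apoptosis regulators rose in 5 of 17 and fell in 6, with a median of -0.07 that became 0.38 with median centring (camera adjusted p = 0.70). The pro-apoptotic gene Bbc3 (1.33 ± 0.06) and the survival gene Bcl2l1 (1.29 ± 0.06) rose next to the fall of Bcl2a1b. Bax (0.02) and Bcl2l11 (-0.06, or 0.63 with median centring and 0.29 as a mean over its probes) were not called.

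**Figure D2:**
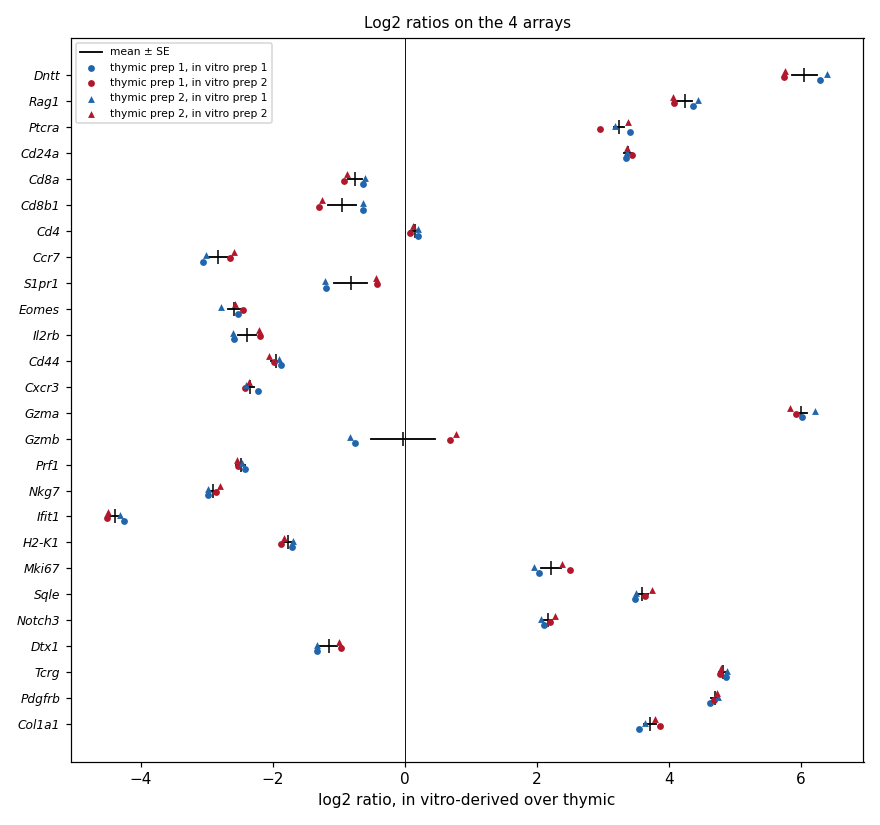
Log2 ratio of in vitro-derived over thymic cells (horizontal axis) on each of the 4 arrays for selected genes (vertical axis); shape gives the thymic prep and colour the in vitro prep, and black lines are the mean ± SE of the fit on preps. The arrays of Dntt sit around 6.05 and those of Ifit1 around -4.39, while Gzmb has opposite signs in the 2 in vitro preps, and Cd8a and Cd8b1 (-0.76 and -0.95) turn to 0.42 and 0.38 with median centring.

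Markers of other cell types were read to see what else the sorted cells held. Markers of OP9-type mesenchymal stroma were higher in in vitro-derived cells in 17 of 20 tested genes and lower in 1, with a median of 1.21 (camera adjusted p = 1.1e-05, and adjusted p = 0.60 with an estimated correlation) that became 2.91 with Agilent's processed signals. The collagen genes Col1a1 (3.71 ± 0.09, 13.1-fold) and Col1a2 (2.94 ± 0.11, 7.69-fold), the chemokine gene Cxcl12 (3.46 ± 0.15, or 5.57 with Agilent's processed signals) and Pdgfrb rose, and Tagln (0.13) and Vcam1 (-0.08) were not called. Markers of natural killer cells and innate lymphocytes rose in 4 of 12 and fell in 4, with a median of 0.20 (camera adjusted p = 0.97, with the test pointing down). Next to the rise of Gzma, the regulator gene Id2 fell by 2.74 (SE 0.08), Cd160 by 0.68 (SE 0.12, or -0.26 and not called with median centring). Klra8 was at least 1.38-fold lower, a call lost with the background fit on all spots and without thymic prep 1. Cd244a (0.42) and Klrb1c (0.34) were not called, but both were without in vitro prep 1 (0.96 and 0.79) and with the thymic prep as a random block. CD4 and regulatory T cell markers rose in 3 of 7 and fell in 3 (median 0.15, camera adjusted p = 0.85). Il2ra and Ctla4 rose, Gpr83 fell by 1.89 (SE 0.09), and Tnfrsf18 fell by 0.88 (SE 0.06) but turned to 0.047 with median centring.

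Myeloid markers rose in 3 of 13 and fell in 5 (median -0.06, camera adjusted p = 0.49), a list that passed with median centring (-0.09). Ctss, a lysosomal protease gene, was 9.62-fold lower (-3.27 ± 0.16), S100a9 4.48-fold lower (-2.16 ± 0.11, or -4.03 with Agilent's processed signals) and the lysozyme gene Lyz2 2.89-fold lower (-1.53 ± 0.22, or -2.41). The mean log2 level of S100a9 in in vitro-derived cells (6.17) was also below that of Klra8, so its fold may be larger. Itgam rose by 0.64 (2.33 with Agilent's processed signals, and not called without thymic prep 2 at 0.62), and Cd14 (0.14) and C1qb (-0.06, or 0.31 with median centring) were not called. B cell markers rose in 2 of 10 and fell in 2, with a median of -0.07 that became 0.02 with median centring (camera adjusted p = 0.85). Blk (1.38 ± 0.13) and Blnk (1.24 ± 0.09) rose, and Cd72 fell by 1.26 (SE 0.18). Cd79b (-0.43) turned to 0.22 with median centring and was not called without thymic prep 1 (-0.42) or prep 2 (-0.44). Vpreb1 (-0.38) was not called, but was without in vitro prep 1 (-0.64), with arrays as independent and with either prep as a random block. Of 10 markers of dendritic cells and MHC class II, 4 rose and 1 fell (median 0.10, camera adjusted p = 0.29). Tcf4 (1.94 ± 0.07) and the class II gene H2-Eb1 (1.02 ± 0.14) rose. H2-Aa (1.14 ± 0.18) and H2-Ab1 (0.74 ± 0.14, or 0.14 as a mean over its probes and 0.71 without thymic prep 2) lost their calls with the background fit on all spots. Another probe of H2-Ab1 was called lower (-0.27). Cd74 (-0.10, or 0.44 with median centring) and Xcr1 (-0.03, or 0.43 with median centring) were not called.

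Erythroid markers rose in 1 of 6 and fell in 1, with a median of 0.06 that became -0.0027 with Agilent's processed signals (camera adjusted p = 0.97, with the test pointing down). The carbonic anhydrase gene Car2 was 8.19-fold lower (-3.03 ± 0.06). Epor (0.31) lost its call with the background fit on all spots and without thymic prep 1 (0.32) or prep 2 (0.30). The globin genes Hba-a1 (0.13) and Hbb-bt (0.00) were not called. Thymic epithelial markers fell in 4 of 10 and rose in 0, with a median of -0.15 that became 0.16 with median centring (camera adjusted p = 0.19). Krt18 fell by 0.84 (SE 0.10), Prss16, a thymus-specific protease gene, was at least 1.63-fold lower. Psmb11 (-0.24) lost its call with the background fit on all spots and without any one of the preps (-0.29 to -0.19), and without array 1 or 4. Ly75 (-0.30) turned to 0.33 with median centring and to 0.063 as a mean over its probes, and Krt14 (0.05) and Ccl25 (-0.08, or 0.55 with median centring) were not called. Of 5 haematopoietic progenitor genes, Lyl1 rose (1.19 ± 0.09) and 0 fell, with a median of -0.04 that became 0.15 with median centring and 0.0074 with Agilent's processed signals (camera adjusted p = 0.91, with the test pointing up). Bcl11a (-0.13) was not called, and neither was Kit (-0.14 ± 0.26), which lay at 0.27 without in vitro prep 1 and at -0.55 without in vitro prep 2.

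Over the 30 lists, 12 passed camera with its preset correlation, 5 higher and 7 lower, and none passed with an estimated correlation, where the smallest adjusted p was 0.42 and 2 lists had an unadjusted p under 0.05. The test with an estimated correlation rests on 2 residual degrees of freedom, so its loss of lists is not due to correlation among members alone. Even the late maturation list, with an estimated correlation of 0.0038, below the preset 0.01, went from a camera adjusted p of 2.9e-06 to 0.42. By fry, which asks only whether the genes of a list move on balance in one direction, 21 lists passed. Counts of members adjusted over the list alone were equal to those over all genes in 25 lists, and the other 5 were given above. The median and the mean differed in sign in 3 lists, those of B cell, erythroid and haematopoietic progenitor markers. Of the 224 gene and list values, 135 moved by over 1.5 times with median centring, and 32 moved as means over probes. Median centring added 30 calls with the sign kept, and a further 27 values turned in sign, some of which also gained or lost a call. Among genes named for their lists, the means over probes were 3.34 for Rag1, 2.79 for Myb, 2.29 for Il2ra, 2.47 for Col1a1, 2.61 for Cxcl12, 1.21 for Tcf4, -1.32 for Cd44, -0.69 for H2-D1, -2.35 for Mx1, -2.80 for Icos, -0.85 for Egr3, -0.78 for Tnfrsf9 and -0.35 for Slc2a3. The calls of Atp5b, Cd28, Cd8b1, Egr3, H2-Aa, Hspa8, Ier2 and Tnfrsf9 also rest on the probe used, as no other probe of these genes was called. For Bcl2, Dnaja1, Il7r and Tyms, another probe was called in the same direction and a further one was not called. Of genes not called, another probe was called higher for Bcl2l11 (0.66), Itgb3 (0.25) and Tagln (0.41), and lower for Lef1 (-0.39), Rpl13 (-0.42), Satb1 (-0.99) and Stat5b.

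Median centring raises the ratios of most genes named here, so that most falls shrink and most rises grow. It takes no account of intensity. Among bright genes, Rpl13 (mean log2 level 17.0 in thymic cells) moved from -0.0083 to 1.36 and Cd3d (16.2) from 0.017 to 1.26. The dim gene Fasl (6.59) moved from -0.073 to -0.26. A sign of a bright gene that turns with median centring can therefore come from this shift, and says little about that gene. The innate-like and memory-like list moved to -1.57 and the interferon response to -1.82. Among genes that stayed lower, it gave -0.44 for Foxo1, -0.43 for Fyn, -0.63 for Hsph1, -0.77 for Il2rg, -0.64 for Il4ra, -0.60 for Cd72, -0.32 for Slc2a3, -1.19 for Gpr83, -2.01 for Ccr7, -1.93 for Cd52, -1.57 for Il2rb, -1.97 for Itgae, -1.91 for Nkg7, -2.16 for Ctsw, -1.94 for Id2, -2.39 for Ctss and -2.79 for Icos. Among genes not called, it added calls for Atf4 (0.91), Bax (0.76), Btg2 (0.97), Cd1d1, Cd69 (1.03), Cox4i1 (1.28), Herpud1 (0.93), Hsp90aa1 (1.27), Itga4 (0.74), Myc (1.15), Pgk1 (1.03), Tagln (0.83), Krt14 (0.44), Hba-a1 (0.52), Hbb-bt (0.40), Hes5 (0.32) and Cd14 (0.37), all higher, and for Fasl (-0.26) and Vcam1 (-0.32), both lower. Agilent's processed signals widened other ratios, among them Blk (2.99), Hes1 (1.87), Hey1 (-3.52), Heyl (1.90), Il2ra (4.31), Lyl1 (1.90), Mx1 (-5.02), Prss16 (-4.03), Klra8 (-2.30) and Socs2 (4.11). The calls lost with the background fit on all spots were also lost with marked spots kept. Among the 224 values, 12 calls were added with arrays as independent, 26 with the thymic prep as a random block and 10 with the in vitro prep as one. Without in vitro prep 1, Herpud1 (0.29) and Myc (0.58) were called, and without in vitro prep 2, Cd1d1 (0.47), Cd74 (-0.22), Hsp90aa1 (0.29), Itgb3 (-0.25) and Lat (0.32). Cd69 was called with prep number as a block and Vcam1 with Agilent's processed signals (-0.32).

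The second comparison was between preps of a kind, which gives the spread the calls rest on. The in vitro-derived preps differed by at least 2-fold in 33 genes, 7 higher in prep 1 and 26 in prep 2, and the thymic preps in 7 genes. Asns lay 2.01 lower in in vitro prep 1 than in prep 2 on the log2 scale (-2.01), followed among the named genes by Gzmb (-1.52), Myo6 (-1.28) and Cd244a (-1.07). Between the thymic preps, Junb was higher in prep 1 (1.59). Over all genes the SD of the difference was 0.196 for the in vitro-derived preps and 0.106 for the thymic preps. Within the in vitro-derived cells the lists of the cell cycle (median -0.31), the unfolded protein and integrated stress responses (-0.30), stromal markers (-0.28) and natural killer markers (-0.24) were higher in prep 2, each below all 10000 random lists of the same size and expression. The genes of the random lists were drawn independently of each other. Extreme percentiles here and below can therefore arise where members of a list vary together, as in the cell cycle (estimated correlation 0.48) and T cell receptor complex (0.89) lists. The T cell receptor complex (0.17, percentile 99.92), interferon response (0.13, percentile 99.95) and immature thymocyte lists (0.16, percentile 99.64) were higher in prep 1. Immediate early genes (0.16, percentile 99.79) were also higher in in vitro prep 1, and innate-like and memory-like genes in prep 2 (-0.17, percentile 0.1), and the other lists lay between percentiles 0.59 and 98.88. Between the thymic preps, immediate early genes (0.39, percentile 100), T cell activation genes (0.09, percentile 100), unfolded protein and integrated stress response genes (0.08, percentile 99.93) and stromal markers (0.06, percentile 99.74) were higher in prep 1. Cell cycle genes were higher in thymic prep 2 (-0.07, percentile 0), and the other lists lay between percentiles 2.9 and 99.29.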

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

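The tests of Cd4 and of the cell cycle given here were chosen after the result was seen; the others were not.

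Of 194 named genes, 6 had 1 array far from the other 3, with a gap above Dixon's 95% critical value for 4 arrays. Chance flags about 1 in 20 where the 4 values are independent. The 4 arrays share preps, so that rate need not hold here. Array 2 held Cd24a at 3.44 (others 3.35 to 3.36), Strip2 at 4.53 (others 4.35 to 4.38) and Oasl2 at -3.23 (others -3.44 to -3.41). Array 4 held Idi1 at 2.72 (others 2.61 to 2.62), array 1 held Psmb11 at -0.37 (others -0.21 to -0.19) and array 3 held Tap1 at -1.12 (others -1.05 to -1.04).

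Markers of stromal cells were higher in in vitro-derived cells, which grew on OP9 stroma. A technical explanation, that the ratios of dim probes come from the background correction, is not decided. Of the 17 higher markers 94.12% were still called higher with Agilent's processed signals, above the 80% set beforehand. Most calls were kept in general, however, as 8944 of all 9975 called genes kept their call and direction. The size of the ratios did depend on the correction, as the list median moved from 1.21 to 2.91 and Cxcl12 from 3.46 to 5.57. Carry-over of OP9 cells through the sort may contribute and is not decided. Of a further list of 16 stromal genes 81.25% were called higher, with Igfbp4 alone lower, and 13 of the 16 lay higher in in vitro prep 2. Col1a1 rose from 7.70 to 11.4 and Col1a2 from 8.22 to 11.2 in mean log2 level. Other markers did not rise: Acta2 fell from 14.5 to 13.6, and Vcam1 lay at 6.52 in thymic and 6.44 in in vitro-derived cells. Dll1, Dcn, Pdgfra and Lum were not tested, being well above background on 0 in vitro arrays, or on 1 for Lum. A sort for CD8 and high T cell receptor beta would also remove such cells. In thymic cells 11 of the 20 markers and 8 of the 16 further genes were also well above background on all arrays, and no gene is shared with another fixed list. The remaining genes of both lists passed the filter only through their signal in in vitro-derived cells, so they could hardly be called lower. This raises the share called higher, which therefore decides little about carry-over. Among all 19154 tested genes 5115 were called higher. Expression of some of these genes by the T cells themselves was not tested, and dye bias stays open because the dyes were not swapped.

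Immature thymocyte genes were higher in in vitro-derived cells. Carry-over of CD4 and CD8 double-positive cells through the sort cannot be told apart from expression by the sorted cells: Cd4, which such cells carry, differed by 0.147 (95% limits -0.018 to 0.31), but it was called with median centring (0.40), its other probe was called higher, and thymic cells also gave Cd4 signal well above background, which could hide a small share. A sort on high T cell receptor beta would remove most such cells, which carry little of it, while the sort on CD8 would not. Cycling alone might carry the list and is not decided. The median of the immature list exceeded that of the cell cycle list by 1.65, within the 1.72 set for the spread of the members. The medians of 2 different lists cannot show, however, whether cycling raises the immature genes. Immature genes lay higher in in vitro prep 1 (0.16) and cell cycle genes in prep 2 (-0.31), which runs against cycling alone but rests on 1 pair of preps. A difference that goes with the origin of the cells, in vitro or thymic, which the design names, stays open and untested.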

How the results depend on the processing

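Leaving marked spots out before the background fit, as for the values reported, was chosen after a first pass with the fit on all spots had been seen, and that fit was then added as an alternative; the other settings were planned. A slide or scan block was not run, because all arrays share 1 slide and 1 scan. The cause of a change was not tested unless stated. Signal over background can limit the size of dim ratios, which was not measured here. With Agilent's processed signals 29 of 224 gene and list values moved by over 1.5 times, against 135 with median centring and 32 with the mean over probes. With the sign kept, median centring gained 30 calls and lost 6, and the mean over probes gained 5 and lost 5. A further 27 and 6 values turned in sign, some of which also gained or lost a call. Of the 2147 calls of at least 2-fold, 1978 to 2147 were called in the same direction under every setting, fewest with the filter on both channels, which tests fewer genes. Prep numbers do not pair the samples (correlation across genes of the prep differences 0.126), and the fit with prep number as a replicate block called 10275 genes. With arrays as independent 13244 were called, with the thymic prep as random block 14876 (correlation -0.51), 8046 of them higher, and with the in vitro prep 11625 (correlation 0.55).

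Median centring gave 13716 calls, 11539 higher and 2177 lower, 4066 of at least 2-fold. It turned the T cell receptor list to 0.40, Bcl2 to 0.24, Bcl2l11 to 0.63, C1qb to 0.31, Ccl25 to 0.55, Cd3e to 0.26, Cd3g to 0.44, Cd74 to 0.44, Cd79b to 0.22, Cd8a to 0.42, Cd8b1 to 0.38, Cox5a to 0.99, Dnaja1 to 0.40, Hspa5 to 0.18, Hspe1 to 0.31, Ier2 to 0.21, Itgb3 to 0.58, Ldha to 1.14, Lef1 to 0.98, Ly75 to 0.33, Mcm2 to 0.76, Ndufa4 to 0.44, Ptprc to 0.36, Rpl13 to 1.36, Socs3 to 0.68, Tnfrsf18 to 0.047 and Xcr1 to 0.43. The mean over probes turned Bcl2l11 to 0.29, Klf2 to -1.07, Ly75 to 0.063, Rpl11 to -0.22, Satb1 to -0.40 and Stat5b to -0.23.

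Agilent's processed signals and the deposited values each gave 3319 calls of at least 2-fold. The background fit on all spots called 7427 genes (46.7% higher) and marked spots kept 7414, and 10 and 11 named genes and lists lost their calls. An estimated correlation, on 2 residual degrees of freedom, left 0 lists past camera and fry gave 21. Leaving out 1 prep or array, with the lone prep assumed to vary like the others, gave 5800 to 9995 calls, 2939 to 5188 higher and 2861 to 4807 lower, lowest without thymic prep 2 (5800) and thymic prep 1 (6067). Gzmb ranged from -0.79 without in vitro prep 2 to 0.73 without prep 1, Kit likewise from -0.55 to 0.27, and Junb from -0.98 without thymic prep 2 to 0.61 without thymic prep 1. The SD between in vitro-derived preps was 0.202 with no background correction, 0.285 with processed signals and with deposited values, 0.221 with an offset of 16, 0.213 with median centring, 0.206 with Aquantile, 0.173 with no filter, 0.197 with both channels, 0.231 with marked spots kept, 0.185 as a mean over probes and 0.230 with the fit on all spots. Between thymic preps it was 0.108 with no correction and with no filter, 0.192 with processed signals and with deposited values, 0.130 with an offset of 16, 0.120 with Aquantile, 0.164 with marked spots kept, 0.104 as a mean over probes and 0.163 with the fit on all spots.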

Other observations

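The test of the further gamma delta list given here was chosen before its result was seen; the genes named by locus and Cd163l1 were chosen after their values were seen.

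Transcripts of the T cell receptor loci moved apart. The 3 probes named Tcra were lower in in vitro-derived cells (-0.79 to -1.55), though with median centring they lay at 0.12, -0.071 and -0.56. The 5 probes named Tcrb-V13 were higher (0.45 to 1.23), and the 3 probes named Tcrg (3.58 to 4.82), with Tcrg-V2 (3.51), were higher by far more. With the background fit on all spots, Cd163l1, a scavenger receptor gene known from gamma delta T cells, was higher by 5.71 (adjusted p = 1.7e-04); it was not tested with the marked spots left out first, because of a non-uniform background, and it would have been among the 15 largest increases.

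Gamma delta T cells among the sorted cells are a candidate explanation for the T cell receptor gamma transcripts. Of a further list of 9 tested genes of gamma delta cells, fixed before its values were seen, 66.67% were called higher and 0 lower, with 5830411N06Rik at 2.56 and Sox13 at 1.15, which lies between the 75% set as needed and the share set as excluding, so the test does not decide. In thymic cells 7 of the 9 were well above background on all arrays. The remaining genes passed the filter only through their signal in in vitro-derived cells, so they could hardly be called lower. A sort on high T cell receptor beta would remove gamma delta cells. Transcription of the gamma locus in alpha beta cells was not tested.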
